A study of Homo sapiens with 59 samples.

How the data were processed

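Gene expression was measured with 59 Affymetrix arrays on RNA from HuH7 cells, an established human hepatoma line. The cells received 1 of 14 antisense oligonucleotides, known here only by SPC code, or a mock transfection without oligonucleotide. Each oligonucleotide was given at 5 nM with lipofectamine at 5 µg per ml for 4 h. The medium was then changed, and the cells were kept for 6 h or 20 h more, so that RNA was taken at 10 h and at 24 h from the start. The 15 treatments and 2 times made 30 groups. Each group held 2 arrays labelled as biological replicates, except SPC4399 at 10 h, which held 1 array. The number of arrays limits the precision: the median standard error of a difference between groups of 2 arrays was 0.12 on the log2 scale. Targets and sequences of the oligonucleotides are not given in the sources used here.

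The deposited values were 1 table of 43483 probe sets by 59 arrays, and the values are in log2 units as the authors deposited them. Per the submitters' processing notes the arrays were read with the affy package, with no version given. The background correction, normalization and summary method are not given in the sources used here. The array medians lay between 4.88 and 5.00, and the values were used as deposited without further scaling. Scanner files and detection calls were not used here. The platform's annotation gave 1 gene symbol to 25919 probe sets and several symbols to 0. The 17564 probe sets with no symbol were left out of the comparisons and were tested only as an additional observation. A gene was represented by its probe set with the highest mean over all arrays, which gave 17885 genes, 5867 of them with more than 1 probe set. Symbols are printed as the annotation gives them, older ones such as IL8 included.

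Differences were tested with limma 3.58.1 in R 4.3.3, with the data.table package in version 1.17.8 and matplotlib 3.10.9 for plots. A single model with a mean for each of the 30 groups was fitted over all 59 arrays, with moderated variances. It had 29 residual degrees of freedom and 5.00 prior degrees of freedom. A group of 1 array was assumed to vary like the others. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over genes within each comparison, and a gene was called at an adjusted p below 0.05. Fold changes are log2 differences with standard errors (SE).

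The comparisons were each oligonucleotide against mock at the same time, the mean of the 14 against mock, and each oligonucleotide against the mean of the other 13. A gene was counted as specific to an oligonucleotide when it was called in that last comparison at both times with 1 sign. An F test asked whether the 14 oligonucleotides differed at a given time. Changes from 10 h to 24 h were tested in mock and over the mean of the 15 treatments, and an interaction tested whether an effect differed between the times. The replicate numbers were checked for pairing with mock. The correlation of replicate deviations with those of mock, across genes, had a median of 0.0344 over 27 groups and ranged from -0.152 to 0.273. Of these 27 groups 7 lay over 0.1 and 3 under -0.1. Between groups of the same time the median was 0.0120 over 196 pairs, with a highest of 0.478 and 42 over 0.1. Some groups thus shared deviations by replicate number, but most did not, and no block was used; the block was tried as an alternative.

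Genes were grouped in 20 lists: interferon response, p53 targets, unfolded protein and integrated stress response, cholesterol biosynthesis and SREBP2 targets, lipogenesis, hepatocyte secreted proteins and identity, acute phase, NF-kB inflammation, cell cycle, hypoxia, miR-122 targets, NRF2 oxidative stress, xenobiotic metabolism, immediate early genes, heat shock, oligonucleotide-binding proteins with RNase H and RNA decay factors, targets of antisense drug programmes, apoptosis regulators, histone genes, and markers of other cell types. Lists were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over lists and comparisons, and again with an estimated correlation. Camera compares a list with all other genes. Members past the threshold were counted over all genes and adjusted over the list alone.

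The tests, the lists and the naming rule were fixed before the data were examined. The rule named up to 10 increases and 10 decreases of the mean of the 14 at each time. For each oligonucleotide it named the extreme genes called at both times both against mock and against the other 13. It also named antisense drug programme targets called at both times, up to 4 members of each called list, and the 5 largest increases and decreases over time in mock. Genes named outside it are described as chosen after their values were seen. Sets taken from 1 oligonucleotide and tested in the others, and the direct differences between pairs of oligonucleotides, were also chosen after the values were seen.

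The alternatives fixed with the tests were a filter keeping the upper 50% of genes by mean, a second quantile normalization, the replicate number as a block, the mean of all probe sets of a gene, a fit to the arrays of 1 time alone, array weights, and leaving out each array in turn. The standard deviation (SD) of each array as a covariate, and leaving out SPC4394 at 10 h replicate 1 in comparisons that do not contain that array, were added after the data were seen. So were a shortened miR-17 target list and the set tests without single arrays, in which 1 p-value at a time was replaced before adjustment. The calls were tested on simulated data with 17885 genes, 200 of them changed. For SPC4388 at 10 h against mock, 60.5% of genes changed by 0.5 on the log2 scale and 99% of genes changed by 1 were recovered. For SPC4399 at 10 h, with 1 array, the shares were 33% and 96.5%. For the mean of the 14 at 24 h they were 88.5% and 99.5%, and for genes specific to SPC4388 at both times 86% and 99%. Camera called the shifted list and 0 of 50 unchanged lists in the simulation of SPC4388 at 10 h. The simulated genes varied independently, so this does not test the preset correlation on lists whose members vary together.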

Results

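HuH7 hepatoma cells carried 1 of 14 antisense oligonucleotides at 5 nM or a mock transfection, and gene expression was read on 59 arrays at 10 h and 24 h. Groups held 2 arrays, except SPC4399 at 10 h with 1. Replicate arrays correlated at r = 0.995 to 0.998 across genes, an r set mostly by the differing levels of genes. The SD over genes of the difference between replicates was 0.154 to 0.270 log2 units. The first principal component held 29.9% of the variance and separated the times, with 10 h arrays from -19.2 to -2.97 and 24 h arrays from 6.97 to 15.6. SPC4394 replicate 1 at 10 h stood apart on the second component, at -26.9, and had the lowest SD of its values, 2.39. The study's stated question was how each oligonucleotide changed expression relative to mock at the 2 times.

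The genes called with SPC4388 at both times rose. TBC1D9, a member of the TBC domain family of Rab regulators, rose by 1.20 log2 units (SE 0.09) at 10 h and 1.21 (SE 0.09) at 24 h, with n = 2 per group. ZNFX1, a helicase that binds double-stranded RNA in antiviral defence, rose by 1.22 and 1.08. Adjusted p was 1.33e-11 and 1.03e-11 for TBC1D9, and 1.73e-13 and 7.55e-12 for ZNFX1. SPC4388 raised 156 genes and lowered 12 against mock at 10 h, and raised 166 and lowered 19 at 24 h. Of these, 85 rose at both times, where chance gives 1.45, and 0 fell at both times. The fold changes at the 2 times correlated at r = 0.336 across genes, which are not independent replicates; over the 14 oligonucleotides r ran from -0.0450 (SPC4394) to 0.435 (SPC4396). Against the other 13 oligonucleotides r was 0.203 for SPC4388.

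Further genes raised by SPC4388 at both times were chosen after their values were seen. TGFBR2, the type II receptor for TGF-beta, rose by 0.94 and 0.86 (SE 0.07), and FYCO1, an adaptor that moves autophagosomes and late endosomes along microtubules, by 0.86 and 1.07 (SE 0.10). The phosphatase gene PTPN4 rose by 1.09 and 1.18, and RASA2, which switches off Ras proteins, by 1.05 and 0.96. ULK1 and ATG16L1, needed to start and extend autophagosomes, rose by 0.52 and 0.49 at 10 h and by 0.44 and 0.52 at 24 h. The circadian clock genes CLOCK and CRY2 rose by 0.73 and 0.72 at 10 h and by 0.67 and 0.58 at 24 h. F3, tissue factor, which starts blood coagulation, rose by 0.86 (adjusted p = 0.0169) and 1.03 (adjusted p = 0.00211). WEE1, a kinase that restrains entry into mitosis, rose by 0.38 at both times.

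At 24 h with SPC4388, the chemokine IL8 rose by 0.96 (adjusted p = 0.000579) and the ligand TGFB2 by 1.02 (SE 0.21, adjusted p = 0.00545). HAMP, the gene for the iron hormone hepcidin, fell by 0.78 (SE 0.11, adjusted p = 4.20e-05). At 10 h the same genes stood at 0.62 for IL8 (adjusted p = 0.0607), 0.62 for TGFB2 (adjusted p = 0.176) and -0.42 for HAMP (adjusted p = 0.0694). These 3 genes were chosen after their values were seen, and the interaction test called 0 genes for SPC4388, with 1041 at an unadjusted p below 0.05 in limma, and 2 and 1 without SPC4388 replicate 1 at 10 h or at 24 h. The list of hepatocyte secreted proteins was called downward at 24 h (camera adjusted p = 0.00409), with 4 of 22 members above 0; adjusted p was 0.878 with an estimated correlation. Over all genes 0 of its members passed, and 2 passed adjusted over the list alone. APOC3 stood at -0.39, FGG at -0.35, APOA1 at -0.32 and the hepatocyte transcription factor CEBPA at -0.30. Without mock replicate 2 at 24 h APOC3 was at -0.24 and APOA1 at -0.21, without mock replicate 1 at -0.53 and -0.44, and FGG was at -0.48 and -0.22 without SPC4388 replicate 1 or 2. The SPC4388 count at 10 h was 122 and 73 without its own replicate 1 or 2 and 62 and 78 without mock replicate 1 or 2; at 24 h the corresponding counts were 90, 87, 91 and 109. With each array's SD as a covariate the 10 h count was 70, and with a second quantile normalization it was 97.

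Against the other 13 oligonucleotides, which leaves the mock arrays out, 90 genes were higher and 1, MGAT2, lower with SPC4388 at both times. At 10 h alone 115 were higher and 10 lower, and at 24 h alone 161 were higher and 168 lower, so the excess of raised genes against mock at 24 h was not seen with this reference. MGAT2, an enzyme of N-glycan synthesis and named after its values were seen, stood at -0.25 at 10 h and -0.28 at 24 h against the others. SPC4399 had 7 such genes, SPC4391 had 5, SPC4396 had 1 and the remaining 10 oligonucleotides had 0. SPC4396's gene was MAP4K3, a kinase of amino acid signalling, at -0.51 and -0.49 (adjusted p = 0.00231 and 0.00452); it too was named after its values were seen. Leaving out single arrays took the SPC4388 count from 91 to 47 and 53 without its 10 h replicates 1 and 2, and to 42 and 48 without its 24 h replicates. The SPC4399 count became 3 and 4 without its 24 h replicates 1 and 2, and the SPC4396 count became 0 without any 1 of its 4 arrays. The F test across the 14 oligonucleotides called 127 genes at 10 h and 117 at 24 h, against 2369 and 1671 at an unadjusted p below 0.05.

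**Figure D1:**
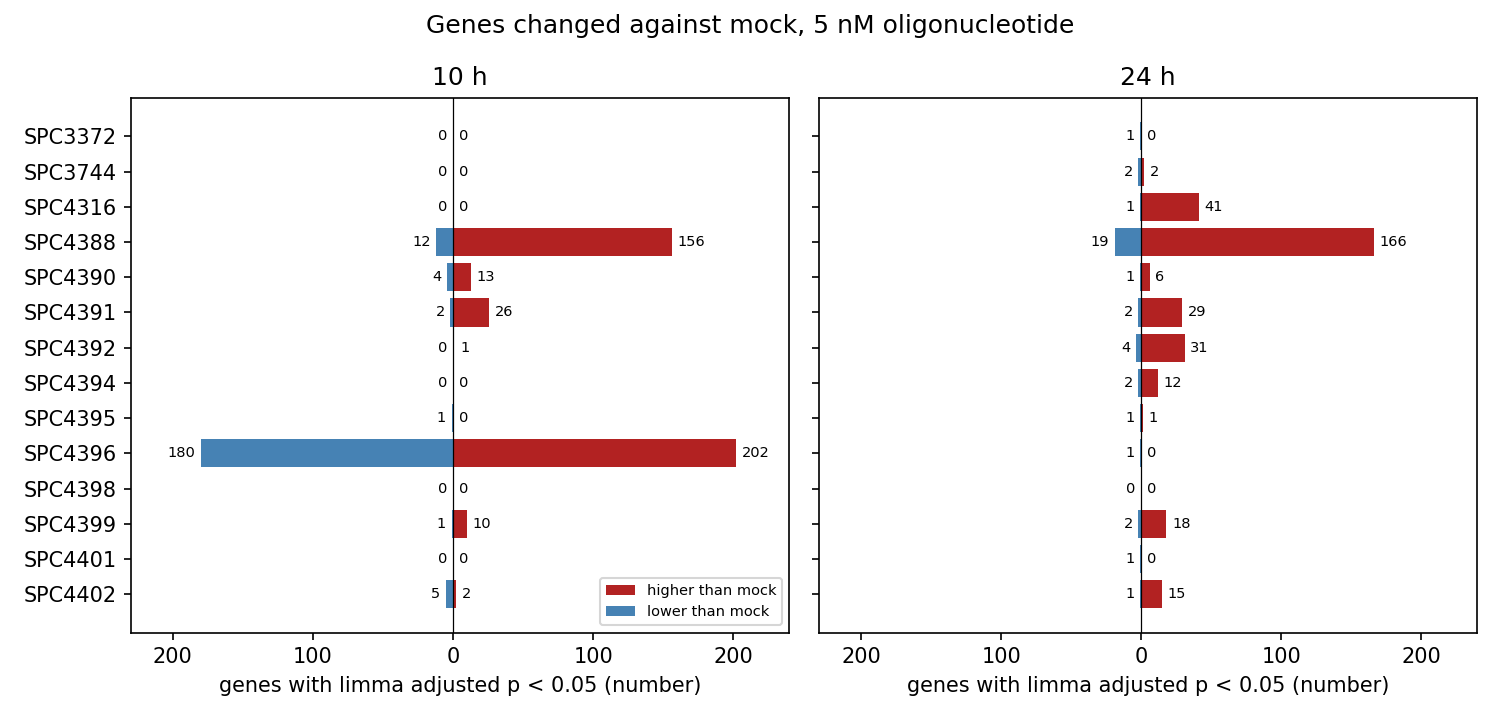
Number of genes raised and lowered against mock (limma, adjusted p below 0.05) for each oligonucleotide at 10 h and 24 h, as bars from 0. SPC4388 has 168 and 185 called genes, and SPC4396 has 382 at 10 h and 1 at 24 h.

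SPC4391 raised several of the genes raised by SPC4388. TBC1D9 rose by 0.83 at 10 h and 0.83 at 24 h, FYCO1 by 0.57 and 0.70, TGFBR2 by 0.54 and 0.56, and ZNFX1 by 0.73 and 0.46. With C7orf43 these were the 5 genes specific to SPC4391; TGFBR2, ZNFX1 and C7orf43 were named after their values were seen. PTPN4 stood at 0.37 (adjusted p = 0.0532) and 0.29 (adjusted p = 0.218) with SPC4391, and RASA2 at 0.28 (adjusted p = 0.532) and 0.18 (adjusted p = 0.916). SPC4391 called 28 genes at 10 h, 26 of them up, and 31 at 24 h, 29 of them up; 9 rose at both times, where chance gives 0.0422. Without SPC4391 replicate 1 or 2 the 10 h count was 13 and 8, and without mock replicate 1 or 2 it was 10 and 8. At 24 h these counts were 4, 6, 17 and 7, and the specific count was 1 and 3 without the 10 h replicates and 1 and 2 without the 24 h replicates.

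SPC4390 and SPC4392 had smaller values for the same genes. TBC1D9 rose with SPC4390 by 0.54 and 0.56, and with SPC4392 it stood at 0.47 (adjusted p = 0.0570) at 10 h and rose by 0.56 at 24 h. FYCO1 rose with SPC4390 by 0.49 and 0.65, and with SPC4392 it stood at 0.33 (adjusted p = 0.914) at 10 h and rose by 0.44 (adjusted p = 0.0493) at 24 h. The 90 genes raised with SPC4388 were tested as a set in each oligonucleotide against the mean of the remaining 12, a test chosen after the values were seen. With SPC4391, 90 of 90 genes were higher at 10 h (median 0.23) and 84 at 24 h (median 0.16), with camera adjusted p of 5.71e-90 and 3.17e-51; with an estimated correlation the adjusted p was 3.36e-07 and 1.74e-05. With SPC4390, 87 genes were higher at each time (medians 0.15 and 0.11), with adjusted p = 0.00142 and 5.35e-05 with an estimated correlation. With SPC4392, 73 and 85 genes were higher (medians 0.07 and 0.12), with adjusted p = 0.0418 and 0.00114 with an estimated correlation. At 10 h that SPC4392 call ended without its replicate 1 (0.06, adjusted p = 0.168) or 2 (0.08, adjusted p = 0.123), and the other 5 calls held without any 1 array of the oligonucleotide.

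With an estimated correlation the same 90 genes were called lower than in the remaining 12 with 5 other oligonucleotides. Each of these 6 calls ended without 1 array of the oligonucleotide. The medians were -0.11 for SPC3372, -0.15 for SPC4394 and -0.08 for SPC4395 at 10 h, with adjusted p = 0.0141, 0.0120 and 0.0435 with an estimated correlation. At 24 h they were -0.06 for SPC3372, -0.08 for SPC3744 and -0.08 for SPC4399, with adjusted p = 0.0435, 0.0414 and 0.0435 in that order. Without replicate 1, the array that stood apart, SPC4394 at 10 h had a median of -0.07 (adjusted p = 0.0781 with an estimated correlation), and -0.23 without replicate 2. SPC3372 at 10 h was at -0.09 without its replicate 2 (adjusted p = 0.0967). Without replicate 1 or 2 the adjusted p was 0.0749 and 0.279 for SPC4395 at 10 h (medians -0.10 and -0.05), and at 24 h 0.164 and 0.162 for SPC3372, 0.0547 and 0.238 for SPC3744 and 0.0749 and 0.313 for SPC4399. At the preset correlation SPC4316, SPC4401 and SPC4402 at both times, and SPC4395, SPC4396 and SPC4398 at 24 h, were also called lower. Their medians lay from -0.05 to -0.02. The reference of 12 held SPC4391, SPC4390 and SPC4392, in which the set was raised.

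**Figure D2:**
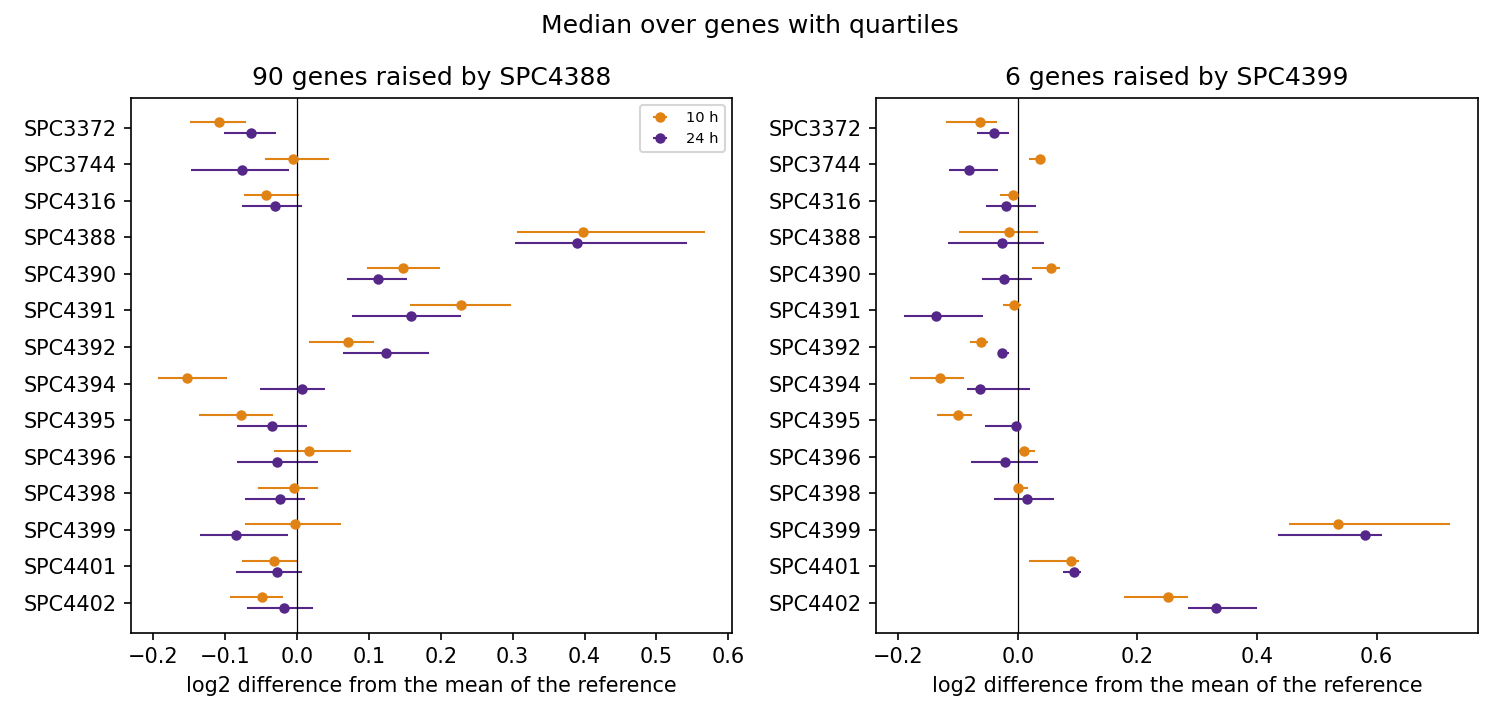
Median log2 difference, with quartiles over genes, of the 90 genes raised by SPC4388 and the 6 raised by SPC4399, in each oligonucleotide against the mean of the remaining ones at 10 h and 24 h. For the 90 genes SPC4391 lies at 0.23 and 0.16, and for the 6 genes SPC4402 lies at 0.25 and 0.33.

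Direct differences between these oligonucleotides, at matched dose and time, were sought after the values were seen. ZNFX1 was higher with SPC4388 than with SPC4391 by 0.49 (95% interval 0.34 to 0.64, adjusted p = 0.00128) at 10 h and 0.62 (0.47 to 0.77, adjusted p = 9.17e-06) at 24 h. TGFBR2 was higher by 0.40 (0.26 to 0.54, adjusted p = 0.00590) at 10 h, and its difference at 24 h was 0.30 (0.16 to 0.44, adjusted p = 0.0749). For TBC1D9 the differences were 0.37 (0.19 to 0.55, adjusted p = 0.239) and 0.38 (0.20 to 0.56, adjusted p = 0.0851). SPC4388 exceeded SPC4391 for 4 genes at 10 h and 16 at 24 h, and was lower for 0 and 4. Between SPC4391 and SPC4390 limma called 0 genes at either time, with 640 and 629 at an unadjusted p below 0.05. TBC1D9 differed there by 0.29 (0.11 to 0.47, adjusted p = 1.00) and 0.27 (0.09 to 0.45, adjusted p = 1.00). Between SPC4391 and SPC4392 limma called 1 gene higher and 1 lower at 10 h, and 0 at 24 h with 1231 at an unadjusted p below 0.05. ZNFX1 was higher there by 0.47 (0.32 to 0.62, adjusted p = 0.00600) at 10 h, and its difference at 24 h was 0.16 (0.0053 to 0.31, adjusted p = 0.714). Between SPC4390 and SPC4392 limma called 2 genes higher and 2 lower at 10 h, and 0 at 24 h with 655 at an unadjusted p below 0.05. TBC1D9 differed between these by 0.08 (-0.10 to 0.25, adjusted p = 0.804) at 10 h and 0.00 (-0.18 to 0.18, adjusted p = 0.999) at 24 h, and ZNFX1 by 0.26 (0.11 to 0.41, adjusted p = 0.357) at 10 h.

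SPC4399 raised another set of genes. IL1R1, the signalling receptor for interleukin-1, rose by 0.87 (SE 0.11, adjusted p = 2.09e-05) at 10 h, with 1 array against 2, and by 1.00 (SE 0.09, adjusted p = 8.70e-09) at 24 h. SESN3, a sestrin that restrains mTORC1 under stress, rose by 0.91 (SE 0.18, adjusted p = 0.0254) and 0.79 (SE 0.14, adjusted p = 0.00519). Chosen after their values were seen, LONRF1 rose by 0.75 and 0.62, UHMK1 by 0.65 and 0.75, and TNFRSF12A, the receptor for TWEAK, by 0.52 and 0.59. SPC4399 called 11 genes at 10 h and 20 at 24 h, and 10 rose at both times, where chance gives 0.0101. The 24 h count was 11 and 28 without SPC4399 replicate 1 or 2, and 6 and 13 without mock replicate 1 or 2; the 10 h count was 6 without either mock array. The SESN3 call at 24 h ended without SPC4399 replicate 1 (0.68), mock replicate 1 (0.73) or mock replicate 2 (0.84).

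SPC4402 shared part of the SPC4399 set. LONRF1 rose by 0.48 and 0.57, TNFRSF12A by 0.36 and 0.36, and IL1R1 stood at 0.41 (adjusted p = 0.0759) at 10 h and rose by 0.57 (adjusted p = 0.00208) at 24 h. SESN3 stood at 0.06 and 0.11. In a set test chosen after the values were seen, 5 of the 6 genes raised by SPC4399 were higher with SPC4402 than with the remaining 12 at each time, with medians of 0.25 and 0.33. Adjusted p was 1.06e-05 and 6.22e-07 with an estimated correlation. SPC4401 had medians of 0.09 and 0.09, with adjusted p = 0.0435 and 0.0175 with an estimated correlation. With SPC4391 at 24 h 0 of the 6 genes were higher, with a median of -0.14 and adjusted p = 0.0408 with an estimated correlation. The SPC4401 call ended at 10 h without its replicate 1 or 2 (adjusted p = 0.342 and 0.0535) and at 24 h without replicate 1 (0.05, adjusted p = 0.241). That of SPC4391 ended without its replicate 2 (-0.07, adjusted p = 0.342), and the SPC4402 calls held without either array. Between SPC4399 and SPC4402 limma called 0 genes at either time, with 784 and 879 at an unadjusted p below 0.05. The difference for SESN3 was 0.85 (95% interval 0.49 to 1.21, adjusted p = 0.275) at 10 h and 0.68 (0.38 to 0.97, adjusted p = 0.188) at 24 h. SPC4402 called 7 genes at 10 h, 2 up and 5 down, and 16 at 24 h, 15 of them up, and 2 rose at both times. The 24 h count was 3 and 0 without SPC4402 replicate 1 or 2, and 10 and 4 without mock replicate 1 or 2; the 10 h count was 1 and 0 without its own and 0 and 1 without the mock replicates.

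**Figure D3:**
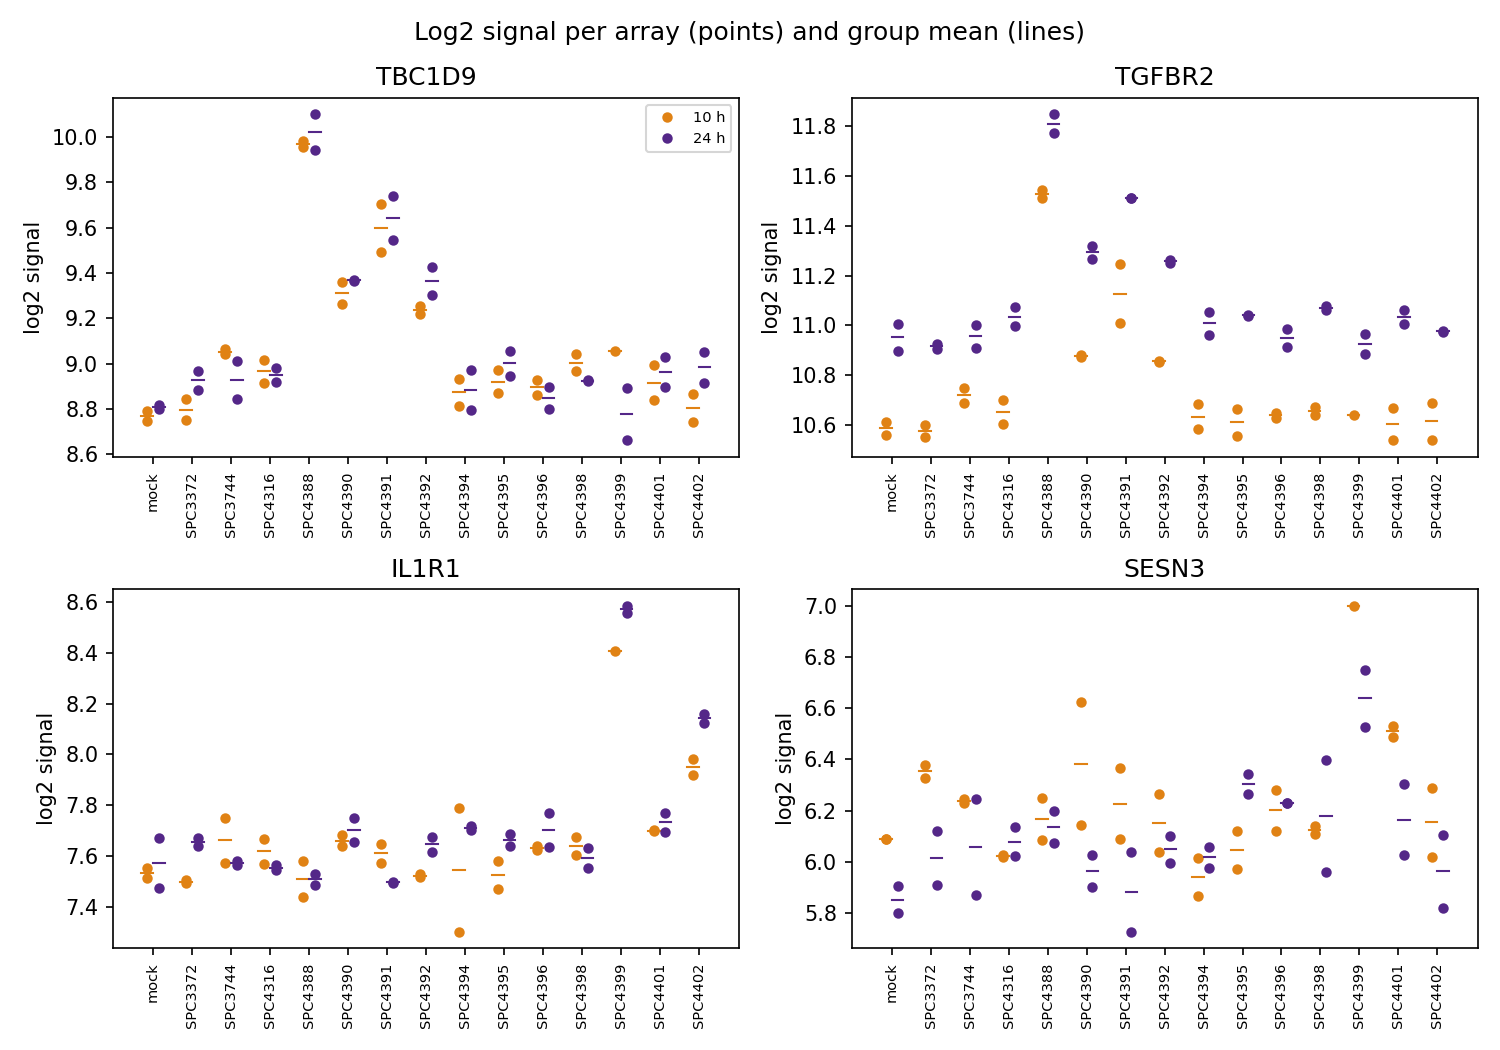
Log2 signal of TBC1D9, TGFBR2, IL1R1 and SESN3 on each array, as points by treatment at 10 h and 24 h. SPC4388 has the highest TBC1D9 group means, 9.97 at 10 h and 10.02 at 24 h, and SPC4399 the highest IL1R1 group means, 8.40 and 8.57.

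With SPC4396 many genes were called at 10 h, each with a modest change. Chosen after their values were seen, CLSTN3, a calsyntenin, rose by 0.80, UGT1A6, which glucuronidates phenols, by 0.66, and HGF, hepatocyte growth factor, by 0.57. The glutamate receptor gene GRIN2A and SYT16 fell, at -0.74 and -0.73. SPC4396 raised 202 genes and lowered 180 at 10 h, and at 24 h the call was GPR139 alone, which fell by 0.67 after standing at -0.32 (adjusted p = 0.0480) at 10 h. The interaction test called 0 genes for SPC4396, with 948 at an unadjusted p below 0.05 in limma. The lowered genes had a median signal of 5.66, against 7.60 for the raised and 6.52 for all genes. The 10 h count was 119 and 9 without SPC4396 replicate 1 or 2, 22 and 5 without mock replicate 1 or 2, and 21 with each array's SD as a covariate.

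SPC4316 raised 41 genes and lowered 1 at 24 h; chosen after their values were seen, IRF2, an interferon regulatory factor, rose by 0.76, CALR, the chaperone calreticulin, by 0.72, and SCAF1 by 0.90. SPC4392 raised 31 and lowered 4 at 24 h, SPC4394 raised 12 and lowered 2, and SPC4390 raised 6 and lowered 1. SPC4390 called 17 genes at 10 h, 13 of them up, and 3 rose at both times. SPC3744 called 4 genes at 24 h: PEBP1, an inhibitor of Raf kinase, rose by 0.61 and GM2A, a cofactor of ganglioside breakdown, by 0.44, while GPR139 and CCDC73 fell, at -0.60 and -0.72. SPC4395 called PIAS3, an inhibitor of STAT3, at 0.36 and GPR139 at 24 h, and the flippase gene ATP8A1 at -0.63 at 10 h. SPC4392 at 10 h called SFRS6, a splicing factor, at 0.61. SPC3372 called GPR139 (-0.55) at 24 h, as did SPC4401 (-0.61). These genes were chosen after their values were seen. The counts of SPC3372 at 24 h and of SPC4395 at each time became 0 without any 1 of their own or the mock arrays, and that of SPC4401 at 24 h without either of its own arrays or mock replicate 2.

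Limma called 0 genes at 10 h for SPC3372, SPC3744, SPC4316, SPC4394, SPC4398 and SPC4401, with 399, 1908, 1144, 1158, 1766 and 1102 at an unadjusted p below 0.05, and 0 for SPC4398 at 24 h, with 2141. Single arrays decided some of these counts. Without SPC4394 replicate 2 at 10 h the count became 239, and without SPC3744 replicate 2 at 24 h it became 430. SPC4316 at 24 h had 0 genes without its replicate 2 or without mock replicate 2, and SPC4392 at 24 h had 2 and 8 without its replicates 1 and 2 and 0 and 12 without those of mock. SPC3744 at 24 h had 0 genes without its replicate 1 or mock replicate 2, and 11 without mock replicate 1. SPC4390 had 0 and 37 at 10 h without its replicates 1 and 2 and 1 without either mock array, and at 24 h 1 and 2 without its own and 0 without either mock array. SPC4394 at 24 h had 0 without any 1 of its own or the mock arrays. Without SPC4394 replicate 1 at 10 h, which enters the shared estimate of spread, SPC4390 had 36 at 10 h, SPC4394 had 24 at 24 h and SPC4398 had 4 at 24 h.

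The mean of the 14 oligonucleotides was compared with mock. At 24 h GPR139, an orphan receptor gene of the brain, fell by 0.53 (SE 0.06, adjusted p = 2.04e-05), and it was called in 13 of the 14 oligonucleotides, the exception being SPC4398. Its mean signal was 4.27, above 24.1% of genes, and in mock GPR139 rose by 0.38 from 10 h to 24 h (adjusted p = 0.00587). LIMK1, the kinase that inactivates cofilin, rose by 0.50 (adjusted p = 0.0235), AOF1, a histone demethylase, by 0.54 (adjusted p = 0.0122), and LRP12 by 0.39 (adjusted p = 0.00676). TTC26, a component of ciliary transport, rose by 0.48, ABHD7 by 0.47, SEC16B by 0.46 and LPHN3 by 0.43. With the mean of all probe sets of a gene LPHN3 stood at 0.04 (adjusted p = 0.871), TTC26 at 0.39 (adjusted p = 0.0790) and MARCH6 at 0.24 (adjusted p = 0.135). VANGL1, a planar polarity gene, rose by 0.41, MARCH6, a ubiquitin ligase of the endoplasmic reticulum, by 0.37, and MAPK13, a p38 kinase, by 0.37 (adjusted p = 0.0483). In all, 24 genes rose and 1 fell at 24 h, and 24 of the 25 had 1 sign in all 14 oligonucleotides.

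At 10 h the mean of the 14 raised LILRA2 by 0.48 (SE 0.09), the myelin gene MBP by 0.38, the phosphatase gene PTPN21 by 0.35 and TBC1D9 by 0.33, and ATP8A1 fell by 0.42 (SE 0.08), each with adjusted p = 0.0395. All 5 had 1 sign in all 14 oligonucleotides, which share the 2 mock arrays and from whose mean the genes were chosen. The mean signal of LILRA2 was 2.98, above 6.90% of genes, so its change lies near the lower end of the range of signals. TBC1D9 stood at 1.20, 0.83, 0.54 and 0.47 with SPC4388, SPC4391, SPC4390 and SPC4392, and from 0.03 with SPC3372 to 0.29 with SPC4399 in the other 10. With the mean of all probe sets of a gene the count was 1, and the calls ended for ATP8A1 (-0.11, adjusted p = 0.448), MBP (0.16, adjusted p = 0.298), PTPN21 (0.21, adjusted p = 0.228) and LILRA2 (0.48, adjusted p = 0.0880). These comparisons rest on 2 mock arrays per time. Without mock replicate 1 or 2 the count was 0 and 0 at 10 h, and 2 and 3 at 24 h; GPR139 stayed called at 24 h without either. With each array's SD as a covariate the count was 0 at 10 h and 1 at 24 h, and with the replicate block it was 1 at 10 h. Without SPC4394 replicate 1 at 10 h the counts were 19 and 57. The 10 h count was also 0 without replicate 1 of SPC4316, SPC4392 or SPC4395, replicate 2 of SPC4394, or either replicate of SPC4390, SPC4396, SPC4398 or SPC4401. It was 1 without SPC4316 replicate 2 or either SPC4388 array, 2 without SPC3372 replicate 1 and 3 without SPC4392 replicate 2. The 24 h count was 51 without SPC3744 replicate 2, 52 and 15 without SPC4316 replicates 1 and 2, 40 without SPC4396 replicate 1, 42 and 16 without SPC4398 replicates 1 and 2, 48 without SPC4399 replicate 2, and 16 without replicate 1 of SPC4390 or SPC4392.

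Among the gene lists, immediate early genes, the first to respond to growth and stress signals, were called upward by camera in 10 of 30 comparisons. Over all genes 1 member passed with SPC4396 at 10 h and 0 in the other 9. In the mean of the 14 at 10 h, 16 of 18 members were above 0 (camera adjusted p = 0.0253), with adjusted p = 0.489 with an estimated correlation. In that mean 2 members passed adjusted over the list alone; FOSL1 stood at 0.41, NR4A1 at 0.27, EGR1 at 0.24 and ZFP36 at 0.21. Without mock replicate 1 or 2 FOSL1 was at 0.57 and 0.26. This list was also called at 10 h for SPC3372, SPC4316, SPC4388, SPC4391, SPC4395, SPC4396 and SPC4398, and at 24 h for SPC4388 (adjusted p = 0.00179) and SPC4391. With an estimated correlation the adjusted p was 0.133 for SPC4388 at 24 h and from 0.489 to 0.501 for the others.

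NRF2 targets, which counter oxidative stress, were called upward in the mean of the 14 at 24 h (13 of 17 above 0, adjusted p = 0.0469), with adjusted p = 0.878 with an estimated correlation. Over all genes 0 passed, and 3 passed adjusted over the list alone. GCLC, which starts glutathione synthesis, stood at 0.22, OSGIN1 at 0.18, TKT at 0.16 and SRXN1 at 0.15; OSGIN1 was at 0.0096 without mock replicate 2 and 0.34 without mock replicate 1. This list was also called at 24 h for SPC3744, SPC4388 and SPC4398, and SRXN1 passed over all genes with SPC4388, at 0.26, a call that ended without any 1 of the SPC4388 or mock arrays at 24 h, at values from 0.21 to 0.31. The unfolded protein list was called upward with SPC4316 at 10 h and with SPC4395 and SPC4398 at 24 h, lipogenesis genes with SPC3744 and SPC4398 at 24 h, and miR-122 targets with SPC4398 at 24 h, 20 of 23 above 0. The hepatocyte list was also called downward with SPC4392 at 24 h. In each of these 7 the adjusted p was 0.878 with an estimated correlation, as for NRF2; 0 members passed over all genes, and adjusted over the list alone from 0 to 3 did. Of 600 list tests against mock, 22 passed, and 0 passed with an estimated correlation.

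The other 14 lists were called in 0 of 30 comparisons against mock. The smallest camera adjusted p was 0.353 for the interferon response, 0.101 for p53 targets, 0.243 for cholesterol biosynthesis, 0.167 for acute phase, 0.135 for NF-kB inflammation, 0.135 for cell cycle and 0.0775 for hypoxia. It was 0.269 for xenobiotic metabolism, 0.353 for heat shock, 0.167 for oligonucleotide-binding proteins and RNase H, 0.524 for antisense drug programme targets, 0.167 for apoptosis regulators, 0.0775 for histone genes and 0.229 for markers of other cell types. Of 28 interferon response genes measured, 0 passed over all genes in any of the 30 comparisons, and adjusted over the list alone there were 5 calls up and 2 down.

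Among 25 measured targets of antisense drug programmes, none was called at both times. TGFB2 was called with SPC4388 at 24 h, and ERBB3, a receptor of the EGF receptor family, rose at 10 h by 0.47 with SPC4388 and 0.41 with SPC4391. APOB, the structural protein of low density lipoprotein, ranged from -0.19 to 0.16 over the 28 comparisons, HIF1A from -0.15 to 0.09, BIRC5 from -0.13 to 0.13 and BCL2 from -0.46 to -0.06, none of them called. Pairwise tests between oligonucleotides passed in 3 of 4550, with 242 at an unadjusted p below 0.05. All 3 were TGFB2 at 24 h, higher with SPC4388 than with SPC4394 by 1.10, SPC4398 by 1.05 and SPC4396 by 1.02 (adjusted p = 0.0375, 0.0403 and 0.0411).

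Pairs of oligonucleotides shared part of their fold changes. Over 91 pairs the median r across genes was 0.558 at 10 h and 0.604 at 24 h, where a simulation of unchanged groups sharing the 2 mock arrays gave 0.498; genes are not independent replicates. The median covariance was 0.0120 and 0.0124, against 0.00828 simulated. With disjoint arrays for the members of a pair, mock arrays included, the median r was 0.128 and 0.124, above 0 in 82 and 91 of the 91 pairs. The simulated values already include the sharing of the 2 mock arrays, at the fitted spread, so sharing alone accounts for most of the median r. With disjoint arrays the median covariance, which rests on no shared array, was 0.00469 at 10 h and 0.00467 at 24 h. Disjoint arrays do not remove a difference common to the oligonucleotide arrays. Most of these had a larger SD than both mock arrays of their time, and the SD covariate was not applied to the pairs.

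The change from 10 h to 24 h was tested in mock. Mock cells had also received lipofectamine and a medium change, and no group was left untransfected. Time in culture cannot be told apart from the time since these steps. CCR6, a chemokine receptor, rose by 1.26 (SE 0.12), NAV3 by 1.25, the small nucleolar RNA SNORD45B by 1.20, MYCN, a growth-promoting transcription factor, by 1.15 and C3orf57 by 1.12. Among the genes that fell, GLIPR1 changed by -1.54 (SE 0.11), GBP1, an interferon-induced GTPase, by -1.49, CYP1B1, a target of the aryl hydrocarbon receptor, by -1.46, the semaphorin gene SEMA3C by -1.44 and PGM2L1 by -1.43. In mock 266 genes rose and 817 fell; over the mean of the 15 treatments 3960 rose and 5251 fell. Without mock replicate 1 or 2 at 10 h the mock count of 1083 became 498 and 472, and without those at 24 h it became 566 and 546. The call ended for GBP1 without mock replicate 2 at 10 h (-1.13), for SEMA3C without mock replicate 2 at 24 h (-1.16), and for SNORD45B without any 1 mock array (1.05 without replicate 1 at 24 h).

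Over time in mock 7 of the 20 lists were called, 5 falling and 2 rising, and 0 were called with an estimated correlation. NF-kB targets were lower as a list (4 of 17 called down and 1 up, camera adjusted p = 0.00228). RELB was at -1.20, NFKB2 at -1.07 and the adhesion gene ICAM1 at -0.85, while the chemokine CCL20 rose by 0.59. Heat shock genes were lower as a list (5 of 12 called, camera adjusted p = 0.00438), with HSPB1 at -0.38 and HSPA1A at -0.53. So were NRF2 targets (4 of 17 called, camera adjusted p = 0.00146), with HMOX1 at -0.59 and FTH1 at -0.32. Apoptosis regulators were lower as a list (7 of 15 called, camera adjusted p = 0.00228), with BIK at -0.80 and BMF at -0.66. The p53 targets were also lower as a list (3 of 24 called, camera adjusted p = 0.0330), with DDB2 at -0.58. With an estimated correlation the adjusted p was 0.0712 for NF-kB, 0.102 for heat shock, 0.103 for NRF2, 0.0712 for apoptosis and 0.187 for p53. Lists not called included the unfolded protein response (adjusted p = 0.364), hypoxia (0.731), acute phase (0.383) and interferon response (0.251).

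Histone genes rose as a list over time in mock (3 of 12 called, camera adjusted p = 0.000174), with HIST1H2BC at 0.81 and HIST1H2BD at 0.60. Cell cycle genes were called upward as a list (camera adjusted p = 0.0406), but the members were mixed. Of 23, 12 were above 0, with a median of 0.06, and 5 were called up and 3 down. The members with the largest changes were the transcription factor E2F1 at 0.42 and the replication factors CDC6 at 0.40, MCM3 at 0.39 and PCNA at 0.39. With an estimated correlation the adjusted p was 0.103 for histones and 0.463 for cell cycle. Over the mean of the 15 treatments the same 7 lists were called, and immediate early genes fell as well (12 of 18, adjusted p = 0.0276). With an estimated correlation the adjusted p over the 15 treatments was 0.0712 for NF-kB and apoptosis, 0.103 for histones and immediate early genes, 0.144 for NRF2 and heat shock, 0.146 for p53 and 0.454 for cell cycle. Of the named members, the calls of HMOX1, HSPA1A, HIST1H2BC, E2F1 and CDC6 ended without mock replicate 1 at 10 h, at -0.54, -0.57, 0.60, 0.35 and 0.31, and those of HSPB1, HSPA1A and E2F1 ended without mock replicate 2 at 10 h, at -0.33, -0.48 and 0.50. Without mock replicate 2 at 24 h the calls of HMOX1, HSPA1A, HIST1H2BC, E2F1 and CDC6 ended at -0.57, -0.40, 0.73, 0.39 and 0.33, and without replicate 1 those of HIST1H2BC and E2F1 at 0.88 and 0.46.

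Effects were then compared between the times. The interaction test called 1 gene in limma over the 14 oligonucleotides, CCDC73 with SPC3744, which stood at 0.42 against mock at 10 h (adjusted p = 0.279) and fell by 0.72 at 24 h (adjusted p = 0.00843). For the other 13 oligonucleotides it called 0, with 436 to 1746 genes at an unadjusted p below 0.05. Without SPC4394 replicate 2 at 10 h the interaction count of SPC4394 became 557. The CCDC73 call ended without SPC3744 replicate 2 at 10 h or mock replicate 2 at either time, when the count was 0. The count became 2 and 1 for SPC4388 without its replicate 1 at 10 h or 24 h, and 1 for SPC4394 without its replicate 1 at 24 h and for SPC4399 without its replicate 2 at 24 h. It became 1 for SPC3372 without its replicate 2 or mock replicate 2 at 10 h, for SPC4402 without mock replicate 2 at 24 h, and for SPC4395 and SPC4399 without SPC4394 replicate 1 at 10 h.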

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

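Tests of the array spread as a covariate were chosen after the result was seen. With SPC3744 the effect on 1 gene differed between 10 h and 24 h in an interaction test: CCDC73 had an interaction of -1.14 log2 units (SE 0.17, adjusted p = 0.00194). Probe sets without a gene symbol, which the comparisons of genes did not use, were tested in 28 comparisons with mock on the same arrays, and 11 of these gave calls. Their numbers at 10 h were 87 with SPC4396, 11 with SPC4388, 4 with SPC4394 and 1 with SPC4398. At 24 h they were 19 with SPC3744, 13 with SPC4388, 6 with SPC4392, 4 with SPC4402, 2 with SPC4391, 1 with SPC4316 and 1 with SPC4395. With SPC4388, 5 of these probe sets had the same sign at both times.

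The first pattern weighed was SPC4396, with 382 genes called at 10 h and 1 at 24 h. The median change of the 382 was 0.43 against mock. With each array's SD as a covariate it was 0.34, or 79.2% of that median (quartiles over genes 70.9 and 90.9). The median SE rose from 0.105 to 0.112 and the calls fell to 21. Against the other 13 oligonucleotides the median was 0.23, or 52.5% of that against mock (quartiles 43.7 and 63.5), with the same sign in all 382 and 41 called. The bounds set beforehand were for the median alone, and both medians lie past the bound set against the explanation. The quartiles over genes, a condition outside those bounds, reach across them. The 382 genes were chosen on the SPC4396 arrays, which enter both comparisons. That choice alone keeps part of the change, with its sign, against the other 13. The 52.5% therefore does not count against the mock arrays. Neither the array spread nor the 2 mock arrays at 10 h can be told apart from an effect of SPC4396. At 24 h the same genes had a median of 0.13 with the same sign in 340, and an effect of the oligonucleotide stays open.

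The second pattern was the rise of 85 genes at both times with SPC4388. With the SD covariate 93.3% of the median change was kept (quartiles 86.6 and 96.0). Against the other 13 oligonucleotides 81.3% was kept (quartiles 68.6 and 86.5). The mock arrays do not account for it as the whole cause: without them, 90 genes were higher against the other 13 at both times. The slope on SD is set by differences between replicate arrays. The widest was that of SPC4394 at 10 h, with SDs of 2.39 and 2.48. The test was not repeated without that pair, so it cannot exclude the array spread. A candidate explanation is that SPC4388 relieves repression by the microRNA family of miR-17, miR-20, miR-93 and miR-106. A list of 22 targets of that family, written from general knowledge after the largest changes had pointed to the family, was raised against the other 13 at both times, with the larger camera adjusted p at 2.70e-16 and 0.00340 with an estimated correlation. Without CDKN1A, seen before the list was written, and TGFBR2, F3 and ULK1 the larger adjusted p was 7.92e-09, and 0.0344 with an estimated correlation. This is a hypothesis found and tested on the same arrays, since neither the sequence of SPC4388 nor microRNA levels were in the data used here.

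The third pattern was the difference between the mean of the 14 and mock. With the SD covariate the genes called kept 88.0% of their median change (quartiles 82.5 and 96.1), from 0.36 to 0.31, past the bound set against the array spread. The calls nevertheless ended, from 5 to 0 at 10 h and from 25 to 1 at 24 h, as the folds shrank and the median SE rose from 0.0684 to 0.0746 and from 0.0674 to 0.0701. The slope again rests on differences between replicate arrays, above all SPC4394 at 10 h, so the array spread is not excluded. Of the oligonucleotide arrays, 23 of 27 at 10 h and 24 of 28 at 24 h had a larger SD than both mock arrays, and the transfer of oligonucleotide itself stays open and untested.

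For the change from 10 h to 24 h, 1 of 100 splits of the arrays, the real one, gave as many genes. It gave 9117 in a model of treatment and time, and the highest other gave 1. The other splits leave the time difference in the residual spread, which lowers their counts, so the splits do not by themselves exclude chance. They also cannot separate time from anything else that differed between the 10 h and 24 h arrays.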

How the results depend on the processing

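Choices added after the data were seen were the array SD as a covariate, leaving out SPC4394 replicate 1 at 10 h in comparisons that do not contain it, set tests without single arrays, and a shortened miR-17 list. Among 180 values of named genes, 169 kept their direction and side of the threshold under a second quantile normalization, 174 of 180 under the replicate block and 166 of 180 under the mean of all probe sets; of 3054 with 1 array left out, 2849 did. 2 reversed: FOS with SPC4391 at 24 h was -0.012 without SPC4391 replicate 2 and 0.44 without replicate 1, and VLDLR with SPC4398 at 24 h was -0.016 without SPC4398 replicate 2 and 0.63 without replicate 1. Under the mean of all probe sets LPHN3 stood at 0.04 and ATP8A1 at -0.11. With the filter the correlation across genes of the SPC4394 effects at 10 h and 24 h went from -0.0450 to 0.128. List calls against mock numbered 0 of 600 with an estimated correlation, 19 with the filter and 21 with the block. Array depth here is signal over background, and detection calls were not used. The filter tests fewer genes and the fit to 1 time uses fewer arrays; for the other settings the cause was not tested.

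Counts against mock with the filter on low values were, at 10 h, 1 for SPC3744, 290 for SPC4388, 99 for SPC4390, 103 for SPC4391, 2 for SPC4392, 5 for SPC4395 and 2 for SPC4402. At 24 h they were 0 for SPC3372, 113 for SPC3744, 100 for SPC4316, 14 for SPC4390, 63 for SPC4391, 110 for SPC4392, 49 for SPC4394, 50 for SPC4398, 0 for SPC4401 and 133 for SPC4402. The mean of the 14 gave 21 and 165, the F test at 24 h 243, the SPC3744 interaction 0, and the specific counts 2 for SPC4392 and 1 for SPC4402.

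A second quantile normalization gave, at 10 h, 97 for SPC4388, 6 for SPC4390, 13 for SPC4391, 2 for SPC4392, 5 for SPC4395, 156 for SPC4396, 2 for SPC4402 and 0 for the mean of the 14; at 24 h, 1 for SPC4316, 8 for SPC4392, 0 for SPC4394, 0 for SPC4395, 2 for SPC4396 and 8 for SPC4402. Of the 382 SPC4396 genes 129 were shared, and of the 168 SPC4388 genes at 10 h 90 were. The replicate block gave 2 for SPC4392, 0 for SPC4395 and 1 for the mean of the 14 at 10 h, and an SPC4399 interaction count of 1; 58 other counts stayed within 1.5 times. The mean of all probe sets gave, at 10 h, 10 for SPC4390, 2 for SPC4392, 0 for SPC4395 and 1 for the mean of the 14; at 24 h, 7 for SPC3744, 18 for SPC4316, 12 for SPC4390, 28 for SPC4394, 1 for SPC4395, 4 for SPC4398 and 10 for SPC4402.

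With arrays of 1 time alone the 10 h counts were 86 for SPC4388, 0 for SPC4390, 9 for SPC4391, 0 for SPC4395, 16 for SPC4396, 7 for SPC4399, 3 for SPC4402 and 1 for the mean of the 14. The 24 h counts were 1 for SPC3744, 2 for SPC4316, 4 for SPC4390, 14 for SPC4391, 19 for SPC4392, 22 for SPC4394, 1 for SPC4395, 2 for SPC4396, 2 for SPC4401, 6 for SPC4402 and 12 for the mean of the 14. Array weights gave, at 10 h, 1 for SPC3372, 53 for SPC4391, 2 for SPC4392, 13 for SPC4395, 702 for SPC4396, 18 for SPC4402 and 24 for the mean of the 14; at 24 h, 2 for SPC3744, 14 for SPC4390, 87 for SPC4391, 144 for SPC4394, 2 for SPC4396, 4 for SPC4398, 68 for SPC4402 and 57 for the mean of the 14. The SD covariate gave, at 10 h, 70 for SPC4388, 2 for SPC4390, 12 for SPC4391, 4 for SPC4395, 21 for SPC4396, 1 for SPC4402 and 0 for the mean of the 14; at 24 h, 7 for SPC3744, 0 for SPC4316, 4 for SPC4390, 7 for SPC4392, 0 for SPC4394, 0 for SPC4395, 8 for SPC4402 and 1 for the mean of the 14. It shared 62 of the 168 SPC4388 genes at 10 h, 161 of 185 at 24 h and 12 of the 382 SPC4396 genes.

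Leaving out 1 array gave these lowest and highest counts against mock at 10 h: SPC3372 0 to 1, SPC3744 0 to 2, SPC4388 62 to 202, SPC4390 0 to 37, SPC4391 8 to 40, SPC4394 0 to 239, SPC4395 0 to 1, SPC4396 5 to 516, SPC4399 6 to 11, SPC4402 0 to 10 and the mean of the 14 0 to 19. At 24 h they were SPC3372 0 to 1, SPC3744 0 to 430, SPC4316 0 to 51, SPC4388 87 to 219, SPC4390 0 to 7, SPC4391 4 to 33, SPC4392 0 to 45, SPC4394 0 to 24, SPC4395 0 to 3, SPC4396 1 to 2, SPC4398 0 to 4, SPC4399 6 to 28, SPC4401 0 to 1, SPC4402 0 to 19 and the mean of the 14 2 to 57. The time count in mock was 472 to 1159. Interaction counts were SPC3372 0 to 1, SPC3744 0 to 1, SPC4388 0 to 2, SPC4394 0 to 557, SPC4395 0 to 1, SPC4399 0 to 1 and SPC4402 0 to 1. Specific counts were SPC4388 42 to 97, SPC4391 1 to 5, SPC4392 0 to 2, SPC4396 0 to 1, SPC4399 3 to 7 and SPC4402 0 to 1.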

Other observations

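The microRNA target lists in this part were written after the 6 largest increases and decreases per oligonucleotide had been seen, and the tests on them were chosen after that result. Of the miR-17 list, the values of CDKN1A had been seen by then, and those of the other 21 members were seen later. The targets of the miR-17 family were higher as a list with SPC4388, though most members were not called. Of 22 measured targets, 21 were higher than in the other 13 oligonucleotides at 10 h (median 0.21) and 20 at 24 h (median 0.14). Called at both times were 8. Among those called at neither time, CDKN1A stood at 0.36 and 0.15, E2F1 at 0.30 and 0.12, BMPR2 at 0.03 and 0.03, and BCL2L11 at -0.03 and -0.04. TGFBR2, the TGF-beta receptor, was higher by 0.82 and 0.74, F3, tissue factor, by 0.78 and 0.90, MAP3K2, a kinase of stress signalling, by 0.47 and 0.41, and ULK1, which starts autophagy, by 0.43 and 0.36. PKD2, the polycystin channel, was higher by 0.48 and 0.40, ZBTB4 by 0.34 and 0.31, NAGK by 0.39 and 0.52 and TNFRSF21 by 0.25 and 0.24. The adjusted p was 8.16e-25 and 2.70e-16, and 0.000242 and 0.00340 with an estimated correlation. Without CDKN1A, TGFBR2, F3 and ULK1, a choice made after the values were seen, 17 of 18 targets were higher at 10 h and 16 at 24 h (medians 0.15 and 0.12). The adjusted p was 4.32e-14 and 7.92e-09, and 0.00340 and 0.0344 with an estimated correlation. Since 1 p-value at a time was replaced, the 0.00340 at 10 h is the value of the full list at 24 h, passed on by the adjustment. These values would be consistent with release of miR-17 targets, as a hypothesis.

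With SPC4391 the same list was higher in 20 of 22 genes at 10 h (adjusted p = 4.54e-06) and 18 at 24 h (adjusted p = 1.57e-06), with adjusted p = 0.358 and 0.334 with an estimated correlation. SPC4390 had 17 higher at 24 h (adjusted p = 0.0209), with adjusted p = 0.932 with an estimated correlation. The list was lower with SPC3372 at both times, SPC4394 at 10 h, SPC4396 at 24 h and SPC4399 at 24 h, with 2, 3, 1, 5 and 3 of 22 genes above the others in that order. With an estimated correlation those adjusted p were 0.795, 0.795, 0.795, 0.661 and 0.796. The reference for these included SPC4388 and SPC4391.

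Targets of miR-19 were higher with SPC4399 in 8 of 10 genes at 10 h (adjusted p = 0.0144) and 5 of 10 at 24 h (adjusted p = 0.0209), and with SPC4402 in 9 of 10 at 24 h (adjusted p = 0.0149). With an estimated correlation the adjusted p was 0.734, 0.795 and 0.734. Targets of let-7 and miR-98 were higher with SPC4316 at 24 h in 15 of 17 (adjusted p = 0.0316), with adjusted p = 0.874 with an estimated correlation. The remaining 15 of 18 families gave no call, with a smallest adjusted p of 0.0599. Of 504 tests, 14 passed, 9 of them upward, and 2 passed with an estimated correlation, both for miR-17 and SPC4388.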
